A study of Mus musculus with 104 samples.

How the data were processed

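The samples were grouped by assay, purified population, antibody, genotype and age as the labels give them: bulk RNA from CD133-purified marrow (4 knockout and 4 wild type libraries), single-cell RNA from lineage-negative marrow (1 library per genotype at 4 weeks and at 6 months), and CUT&Tag. CUT&Tag libraries, knockout and wild type, numbered 5 and 5 for H3K27me3, 5 and 4 for H2aK119Ub, 5 and 4 for H3K27Ac, 2 and 2 for H3K4me1 and for H3K4me3, 4 and 4 for RBP1 and 2 and 2 for IgG in CD133 cells. For H3K27me3 and for IgG there were 3 and 3 in each of GP, BMN and PBN, and 2 and 2 in MP. IgG libraries were not analysed here.

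The authors deposited a bulk table of raw read counts per gene symbol for 8 libraries, and per the labels used STAR and DESeq2, with no version or genome build given. The meaning of the filter in its name is not stated, and genes with 0 in every library are present (4928 of 19910). The single-cell files hold UMI counts per gene or antibody tag and cell, from filtered barcodes of Cell Ranger 3.0.2 per the file headers for genes and antibody tags, and each library had been sequenced more than once and combined by the authors. The deposited peak lists give for each peak the fold enrichment as a ratio, and −log10 of the MACS2 q value per the file headers' layout. The labels name Bowtie2, MACS2 and DiffBind without versions. Each list serves both genotypes. Checked against the files, the lowest −log10 q in each deposited list matched the q threshold in its name. Other deposited files hold barcodes, gene and tag names and a note on hashtags, with no measurement.

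Bulk counts were filtered with edgeR's filterByExpr (10859 genes tested), scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust, 2-sided, R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05. Libraries held 8959077 to 10974875 counts and correlated pairwise at 0.974 to 0.991, and the biological coefficient of variation was 0.111. Tested on simulated data (negative binomial counts with the fitted dispersions, 10780 genes), 67 of 100 genes changed 1.5-fold and 78 of 96 changed 2-fold were found. There were 8 false calls. Such counts follow the model of the test itself. Standard errors of log2 fold changes are from the edgeR fit, and CPM are given as mean ± SD over libraries. Before the data were examined, 27 gene lists were written: MYC targets, MYC family and partners, RNA polymerase II subunits, RNA polymerase II pausing and elongation, cytosolic ribosomal proteins, primary granule, secondary and tertiary granule, granulocyte transcription factors, monocyte, dendritic, stem cell, Hox and cofactors, erythroid, megakaryocyte, basophil with mast cell and eosinophil, B lineage, T and NK, plasma cell, stromal and endothelial, cell cycle, Polycomb with BAP1 and ASXL partners, interferon response, inflammatory cytokines and NF-kB, immediate early, p53 response, oxidative phosphorylation, and sex-linked genes. Lists were tested with limma 3.58.1 camera (preset correlation 0.01, 2-sided, adjusted over lists), with the correlation estimated per list and with fry as alternatives, and members were also counted when adjusted over the list alone.

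Cells were assigned to mice by hashtag, each tag's log counts split by Otsu's threshold. Barcodes with more than 1 tag (9.13 to 13.9% per library) or no tag (6.74 to 10.4%) were left out, as were cells under 500 genes or over 10% mitochondrial UMIs and doublets marked by Scrublet. Scrublet marked 36.4 to 49.2% of barcodes with more than 1 tag and 2.66 to 3.81% of those with 1. Cells were clustered in scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1; Python 3.11.15, anndata 0.12.19, python-igraph 0.11.9) and clusters named by the mean scaled level of fixed markers for 15 classes. The names are marker-based, so classes are written as "-like", and 2 of 30 clusters stayed unnamed. Shares per mouse were compared within each age by exact 2-sided permutation tests, whose smallest p is 0.0286 with 4 against 4 mice and 0.1 with 3 against 3. UMIs were summed per mouse and class (at least 10 cells) and tested with edgeR as above in stem and multipotent progenitor-like, neutrophil precursor-like, maturing neutrophil-like and monocyte-like cells, with T and NK-like cells as a reference. Tested on simulated data in 6-month precursor-like cells (10621 genes), 81 of 100 genes changed 1.5-fold and 92 of 98 changed 2-fold were found, with 14 false calls. Median UMIs per cell in knockout and wild type were 1971 and 1634 in maturing cells at 4 weeks, 1758 and 1631 at 6 months, and 8681 and 10024, then 14305 and 13899.5, in precursor-like cells.

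Named bulk genes are Asxl1, the 12 largest and 12 smallest log2 fold changes among genes with ordinary symbols that passed, separated the genotypes in every library and averaged at least 5 CPM, up to 4 members per list by smallest p, and Myc, Csf3r, Cebpe, Gfi1, Mpo, Elane and Hoxa9. Of the list members, those past the threshold and the last 7 genes are named. Single-cell genes are the 8 largest and 8 smallest log2 ratios among genes with at least 200 UMIs per age and a ratio of at least 0.585 in size and of 1 sign at both ages, and single-cell list members are given as counts. Gene span came from the RefSeq annotation of GRCm38.p6, matched by symbol for 99.9% of tested genes. The order of genes along the chromosome of Asxl1 came from it too, and none of its coordinates were set against the peaks. Peaks were compared with bedtools 2.31.1, at least 1 base counting as overlap, H3K27me3 lists at a MACS q of at most 1e-06 and CD133 lists at the authors' thresholds, with the 3 widest H3K27me3 peaks per population. The planned comparison of promoter marks with bulk changes was left out because no build is named for the peaks.

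Alternatives were DESeq2 1.42.0 (its size factors with the edgeR test, and its own Wald test), upper-quartile factors, limma voom, other count filters, a fit without robust dispersion, glmTreat at a fold of 1.2, a replicate block and leaving out each library or mouse. For single cells they were other cell filters, doublets kept, Leiden resolutions 0.5 and 2, classes by marker score, mean per-cell CPM, thinning to 2000 UMIs per cell and leaving out each mouse. For peaks they were other thresholds and a wider overlap. Added after the data were seen were a minimum of 200 genes per cell, clusters without called genes, an edgeR test of cell numbers, change relative to T and NK-like cells and removal of the gene span trend through edgeR offsets. Statistics outside R used SciPy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.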

Results

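Bone marrow of C57BL6/J mice lacking Asxl1 (genotype Asxl1 -/-, called knockout) was measured beside wild type marrow by single-cell RNA sequencing, bulk RNA sequencing and CUT&Tag, in which an antibody directs a transposase to DNA carrying a chromatin mark. ASXL1 is a chromatin protein that activates the histone H2A deubiquitinase BAP1. The 104 samples comprised 92 CUT&Tag libraries, 8 bulk RNA libraries and 4 single-cell libraries. The bulk libraries, 4 knockout and 4 wild type, came from CD133-purified marrow at 6 months and held 8959077 to 10974875 counts each. Each single-cell library held lineage-negative marrow of 1 genotype at 1 age, with the mice told apart by hashtag antibodies, 4 mice per genotype at 4 weeks and 3 per genotype at 6 months. The older single-cell samples carry week 36 in their titles and 6 months as their time point, which is the name used here. At 4 weeks the wild type library held 109750499 UMIs in 17638 cell barcodes and the knockout library 79030481 UMIs in 14903. At 6 months the wild type library held 120520461 UMIs in 16774 barcodes and the knockout library 140730519 in 15951. After filtering, 11864 wild type and 10112 knockout cells remained at 4 weeks, with medians of 4894 and 4566 UMIs, and 12122 wild type and 11671 knockout cells at 6 months, with medians of 4925 and 6848 UMIs. All CUT&Tag samples were taken at 6 months.

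Asxl1 RNA was lower in the knockout in bulk marrow and in most classes of single cells. In CD133-purified marrow it fell from 156 ± 3.98 CPM (mean ± SD, n = 4) to 121 ± 13.5, a log2 fold change of −0.37 ± 0.08 (SE; edgeR adjusted p = 0.00581), and the 4 knockout libraries all lay below the 4 wild type libraries. In single cells at 6 months Asxl1 fell in stem and multipotent progenitor-like cells from 68.0 ± 8.41 to 34.2 ± 0.507 CPM (n = 3; log2 −0.98, edgeR adjusted p = 3.37e-09). It also fell at that age in neutrophil precursor-like cells (log2 −0.97, adjusted p = 6.49e-09) and monocyte-like cells (log2 −0.87, adjusted p = 2.05e-10). At 4 weeks the falls were smaller, with log2 values of −0.44 in stem-like cells (67.2 ± 9.70 against 92.6 ± 6.78 CPM, n = 4; adjusted p = 0.00136), −0.27 in precursor-like cells (0.0164, lost in 3 of the 8 fits that leave out 1 mouse) and −0.28 in monocyte-like cells (0.00553). Maturing neutrophil-like cells had log2 values of −0.48 at 4 weeks (adjusted p = 0.184) and −0.46 at 6 months (0.714), and T and NK-like cells −0.60 (0.175) and −0.52 (0.405). Counts over the whole gene do not show how much intact transcript was left, since a deletion of some exons leaves RNA that still counts. In single cells each genotype and age was 1 library, so those p-values measure spread between mice, and genotype cannot be told apart from library. Relative to T and NK-like cells of the same mice, the 4-week Asxl1 difference was 0.16 in stem-like, 0.30 in precursor-like and 0.31 in monocyte-like cells. None of these passed (edgeR adjusted p = 0.977, 0.982 and 0.968). T and NK-like cells carry the same genotype, so this contrast also takes out a fall that all cells share.

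**Figure D1:**
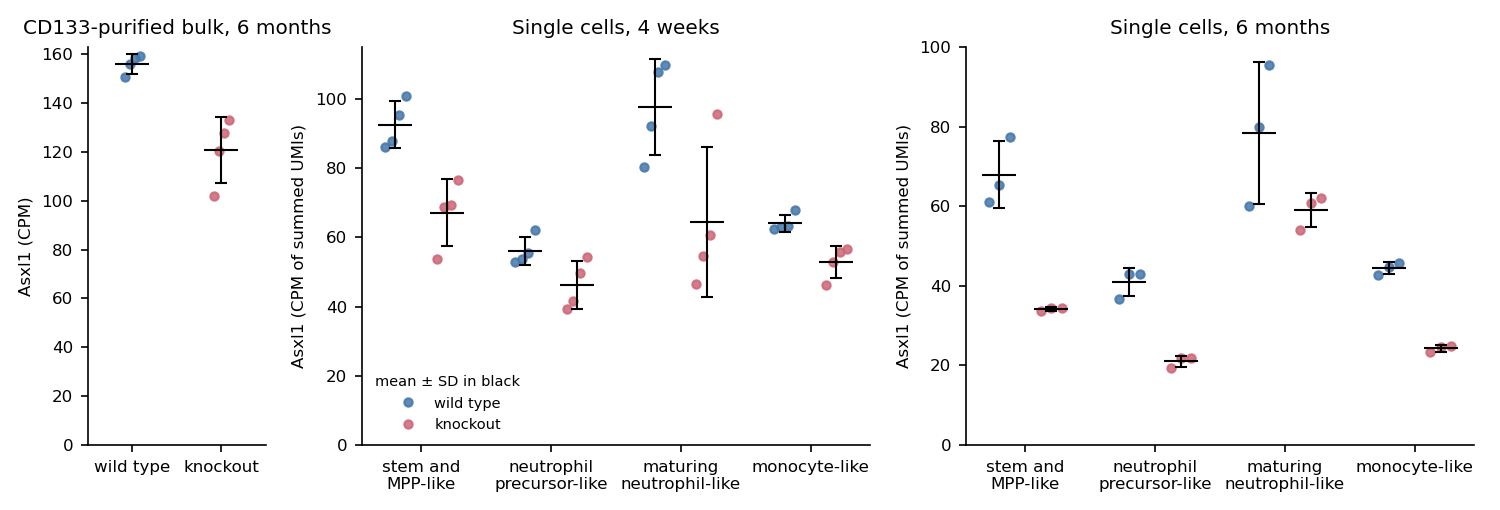
Asxl1 level in CPM for each bulk library (left) and for each mouse in the single-cell classes at both ages, with points for libraries or mice and bars for the mean and SD of each genotype. The 6-month knockout mice lie below the wild type mice in stem and multipotent progenitor-like cells (means 34.2 and 68.0 CPM), and the 4 knockout bulk libraries below the 4 wild type libraries (121 and 156 CPM).

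The bulk comparison addresses how loss of ASXL1 alters the RNA of CD133-purified marrow, in a study that names neutrophil differentiation, MYC and RNA polymerase II as its subject. Of 10859 genes tested, 981 were higher and 969 lower in the knockout (edgeR adjusted p under 0.05), with a median size of 0.35 on the log2 scale among those called. The genes that fell included Cbl, a ubiquitin ligase that ends receptor tyrosine kinase signalling (45.9 ± 7.64 against 127 ± 36.7 CPM; log2 −1.47 ± 0.22 SE, adjusted p = 0.0046), and Ago2, the slicing Argonaute of RNA silencing (34.7 ± 4.82 against 84.6 ± 15.6 CPM; log2 −1.29 ± 0.13, adjusted p = 0.000602). Il6ra, which binds interleukin 6, fell from 43.8 ± 5.0 to 20.8 ± 3.42 CPM (log2 −1.07 ± 0.12, adjusted p = 0.00047). The other large falls were Pdpr, a regulator of pyruvate dehydrogenase phosphatase, at −1.55, Xylt1, which starts proteoglycan sugar chains, at −1.27, and Uhmk1, Lmbrd2 and Trim56, each at −1.11. Ccdc186 and Vgll4, a TEAD cofactor, followed at −1.08 each, then Dhrs9 at −1.06 and Ms4a1, the B cell gene for CD20, at −1.04. The largest rises were in genes of low level: Penk, the precursor of enkephalins (7.70 against 2.55 CPM; log2 1.59 ± 0.24, adjusted p = 0.00137), Tchh at 1.03, and Ager, the receptor for advanced glycation end products (37.3 ± 8.06 against 18.6 ± 1.98 CPM; log2 1.0, adjusted p = 0.00136). They were followed by Fbxl2 at 0.92, Erp27 at 0.91, Ovgp1 at 0.89, Col7a1 at 0.87, Kcnh7 at 0.86, Eno3 at 0.81, Ggnbp1 at 0.80, and Tmprss3 and Stfa1 at 0.79. By the rule that chose them, each of these 24 genes had its 4 knockout libraries all above or all below its 4 wild type libraries, which held for 22.5% of tested genes against 2.86% by chance. The rise genes gave 8 (Kcnh7) to 658 (Eno3) UMIs over the 6-month single cells, and the fall genes 366 (Dhrs9) to 32493 (Cbl), with Ms4a1 at 625 and Ago2 at 26261. The 981 higher genes became 577 without knockout library M2, 540 without M5 and 519 without wild type library W4.

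Fold change in bulk followed the genomic span of the gene. Among the shortest of 5 equal bins of tested genes, with a median span of 4.61 kb, 401 rose and 41 fell, and among the longest bin, with a median of 110 kb, 32 rose and 502 fell. In between, 269 rose and 72 fell at a median of 12.5 kb, 168 and 120 at 23.2 kb, and 111 and 234 at 43.2 kb. Across genes, which are not independent replicates, Spearman's rho of log2 fold change with span was −0.374. Within each library, level relative to the mean of all libraries fell with span in the knockouts (rho −0.26, −0.19, −0.20 and −0.26) and rose with it in the wild types (0.20, 0.18, 0.28 and 0.29). With the trend taken out of each library, 603 genes were higher and 648 lower, of which 482 and 530 were among the first counts. The same relation had the opposite sign in single cells at 4 weeks, with rho from 0.0818 to 0.392 over the classes, and lay between −0.13 and 0.0275 at 6 months.

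**Figure D2:**
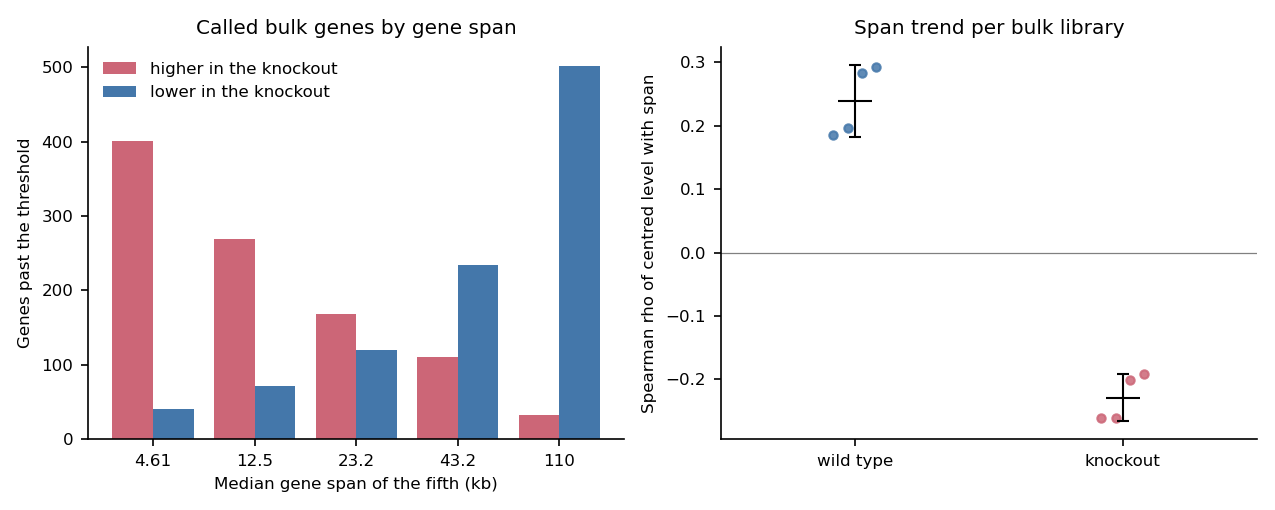
Number of bulk genes higher and lower in the knockout in 5 equal bins of tested genes by genomic span, with the median span in kb on the x axis (left), and the rank correlation of level with span in each library (right). Genes of the shortest bin were mostly higher (401 against 41) and genes of the longest bin mostly lower (32 against 502).

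Cytosolic ribosomal protein genes rose together in the knockout bulk libraries. Of 42 measured members, 29 rose and 13 did not pass the test (34 rose when adjusted over the list alone), with a median log2 fold change of 0.29. Without the span trend 10 rose and the median was 0.17. Rplp2 and Rplp1, which form the ribosomal stalk, rose by 0.71 ± 0.09 and 0.49 ± 0.07 (SE), and Rps24 and Rps15 of the small subunit by 0.56 and 0.43. Oxidative phosphorylation genes moved the same way: 14 of 27 rose and 13 did not pass (16 rose and 2 fell when adjusted over the list alone), with a median of 0.21, and without the span trend 6 rose and 1 fell. Cox6c and Cox5a of cytochrome oxidase rose by 0.46 and 0.40, Uqcrq of complex III by 0.42 and Ndufv2 of complex I by 0.39. Both lists passed camera with its preset correlation (adjusted p = 9.46e-23 for ribosomal proteins and 1.11e-05 for oxidative phosphorylation), the 2 of 27 lists that did. Both calls were lost with an estimated correlation, at an adjusted p = 0.935 for each. Ribosomal protein genes span a median of 3.76 kb against 23.2 kb for all tested genes, and without the span trend the camera adjusted p was 6.5e-08 for them and 0.0493 for oxidative phosphorylation. The 2 lists became 4 without knockout library M4 and 6 without wild type library W5.

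Among the lists that follow from the study's subject, 5 of 40 MYC targets rose and 35 did not pass (4 rose when adjusted over the list alone), with a camera adjusted p of 0.0652. Those that rose included Ppan by 0.65, Gar1 by 0.55, the nucleolar chaperone Npm1 by 0.34 and the nuclear transport GTPase Ran by 0.22. Myc itself had a log2 fold change of −0.15 ± 0.15 (adjusted p = 0.551). Of 12 MYC family and partner genes, the antagonists Mxd4 and Mga fell by 0.60 and 0.43 and Mxd3 rose by 0.30 (1 rise and 2 falls also when adjusted over the list alone; camera adjusted p = 0.512). Of 13 RNA polymerase II subunit genes 4 rose and 2 fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.324). The small subunits Polr2h and Polr2f rose by 0.63 and 0.39, and the largest subunits Polr2a and Polr2b fell by 0.31 and 0.36. Of 33 pausing and elongation genes 3 rose and 6 fell (4 and 7 when adjusted over the list alone; camera adjusted p = 0.512). Aff4 and Aff1, scaffolds of the super elongation complex, fell by 0.57 and 0.43, and Ccnt1 fell by 0.49 while Cdk9, its kinase partner in P-TEFb, rose by 0.38. Without the span trend 2 MYC targets rose, 0 MYC family genes rose and 2 fell, 1 polymerase subunit gene rose and 2 fell, and 1 pausing and elongation gene rose and 4 fell. In the 8 fits that leave out 1 library, the call was lost in 6 for Mxd3, 4 for Polr2f, 3 each for Polr2a and Ran and 1 for Npm1.

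None of the granulocyte lists passed camera in the bulk libraries. Of 14 primary granule and precursor genes, Ms4a3, a marker of granulocyte and monocyte progenitors, rose by 0.30 and 13 did not pass (3 rose when adjusted over the list alone; camera adjusted p = 0.216). The call of Ms4a3 was lost in 7 of the 8 fits that leave out 1 library and kept without W5. The peroxidase gene Mpo, at 0.14 ± 0.17 (adjusted p = 0.626), and the protease gene Elane, at 0.19 ± 0.15 (0.409), did not pass, the latter −0.0052 without the span trend and past the threshold without W5 (0.36). Of 28 secondary and tertiary granule genes, Stfa1 rose by 0.79 and Mmp25, a membrane metalloprotease of neutrophils, fell by 0.51, the same 1 and 1 when adjusted over the list alone. DESeq2 called 7 genes of that list, and 11 had an unadjusted p under 0.05 with edgeR. The list had a median of 0.01, a mean of −0.02 and a downward camera statistic (adjusted p = 0.656). Of 13 granulocyte transcription factors, Klf5 and Runx3 fell by 0.58 and 0.39 and the progenitor factor Myb rose by 0.25, a call lost in 5 of the 8 fits (3 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.676). Csf3r, the G-CSF receptor, had 0.14 ± 0.08 (adjusted p = 0.269), Cebpe −0.10 ± 0.10 (0.499) and Gfi1 0.25 ± 0.10 (0.0955). Hoxa9 was near the detection limit at 1.11 against 1.14 CPM, with −0.06 ± 0.41 (0.946).

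Markers of other cell types in the CD133 gate gave few calls. Mcpt8, a basophil protease, and Ear2, an eosinophil ribonuclease, rose by 0.75 and 0.55 among 9 basophil, mast cell and eosinophil genes (2 also when adjusted over the list alone; camera adjusted p = 0.198). The call of Ear2 was lost in 7 of the 8 fits that leave out 1 library, that of Gp1bb below in 6 and that of Col1a2 in 2. Ms4a1 was the 1 of 15 B lineage genes called, a fall (also 1 when adjusted over the list alone, camera adjusted p = 0.216). Gp1bb was the 1 of 19 megakaryocyte genes called, a rise by 0.42 (camera adjusted p = 0.731). Col1a2, a fibrillar collagen, was the 1 of 11 stromal and endothelial genes called, a fall by 1.15 (1 when adjusted over the list alone, camera adjusted p = 0.198). By sign alone 13 of 15 B lineage, 12 of 19 megakaryocyte, 10 of 11 stromal and endothelial and 7 of 7 plasma cell genes were lower (medians −0.39, −0.15, −0.65 and −0.29). For 8 further lists edgeR called 0 genes, over all genes or adjusted over the list alone, as did limma voom. At an unadjusted p under 0.05, edgeR counted 1 of 24 monocyte genes, 1 of 19 erythroid genes, 1 of 6 Hox and cofactor genes, 2 of 8 T and NK genes, 2 of 4 sex-linked genes, and 0 of 15 dendritic, 0 of 18 stem cell and 0 of 7 plasma cell genes. DESeq2 called 1 T and NK gene and 0 in the others. Their camera adjusted p values were 0.883 (monocyte; median −0.03 and mean −0.02 with an upward statistic), 0.738 (erythroid), 0.512 (Hox), 0.690 (T and NK), 0.676 (sex-linked), 0.902 (dendritic), 0.738 (stem cell) and 0.512 (plasma cell). The Hox list did pass fry, which asks whether its genes move one way on balance (downward, adjusted p = 0.00996).

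None of the chromatin, signalling, stress and cell cycle lists passed camera. Of 33 Polycomb, BAP1 and ASXL partner genes, 3 rose and 6 fell (3 and 7 when adjusted over the list alone; camera adjusted p = 0.512). Asxl2, the paralog of Asxl1, fell by 0.29, as did Foxk2, a DNA-binding BAP1 partner, by 0.32 and Kdm6a, a histone H3K27 demethylase, by 0.32, while the BAP1 partner Mbd6 rose by 0.31. Rel and Nfkb1, both NF-kB subunits, fell by 0.68 and 0.27 and the cytokine gene Tnf rose by 0.31 among 20 inflammatory genes (2 fell when adjusted over the list alone; camera adjusted p = 0.969). Of 28 interferon response genes Stat1 fell by 0.28 and Stat2 rose by 0.29, neither when adjusted over the list alone (5 at an unadjusted p under 0.05; camera adjusted p = 0.246). Of 23 immediate early and stress genes Ier3 and Ier2 rose by 0.49 and 0.26, again not when adjusted over the list alone (4 at an unadjusted p under 0.05; 0.648). Among 16 p53 response genes Perp, a desmosome protein, rose by 0.94 and Ccng1 fell by 0.24 (1 and 1 when adjusted over the list alone; 0.676). Birc5, a mitotic survivin, rose by 0.37, the 1 of 30 cell cycle genes to pass (1 when adjusted over the list alone; 0.676). In the 8 fits that leave out 1 library, the call was lost in 6 for Tnf and Ier2, 5 for Stat1 and Stat2, 4 for Ier3 and 1 for Mbd6 and Ccng1.

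In the single cells, 30 clusters were named by marker genes, and maturing neutrophil-like cells, marked by the granule genes Ltf, Ngp and Camp or by Retnlg, Mmp9 and Il1b, took a lower mean share of knockout marrow at both ages. At 6 months they made up 1.93% ± 0.656 of knockout cells and 12% ± 8.13 of wild type cells (SD, n = 3; 215 and 1421 cells), and the knockout mice (1.24 to 2.55%) lay below the wild type mice (3.70 to 19.9%). The exact two-sided permutation p was 0.1, the smallest that 3 mice against 3 allow. At 4 weeks the shares were 2.53% ± 1.28 and 7.06% ± 7.05 (n = 4; 262 and 802 cells; exact p = 0.286), and the wild type mice ranged from 0.598 to 16.9%. Without wild type mouse 1, the 1 at 0.598%, the 4-week difference was −6.68 points (exact p = 0.0286), and without wild type mouse 4, the 1 at 16.9%, it was −1.25 points (exact p = 0.571), against −4.52 with all mice. An edgeR test of cell numbers gave log2 −2.64 for this class at 6 months (adjusted p = 0.0293) and passed 0 classes at 4 weeks (1 at an unadjusted p under 0.05, basophil and mast-like cells, log2 0.52 with edgeR adjusted p = 0.579). The lineage-negative gate is meant to exclude mature neutrophils, and this class had medians of 1631 to 1971 UMIs per cell, so its share depends on that purification and on the minimum of genes per cell. Genotype cannot be told apart from library here, and the p-values measure spread between mice that all sit in 1 library per genotype and age.

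**Figure D3:**
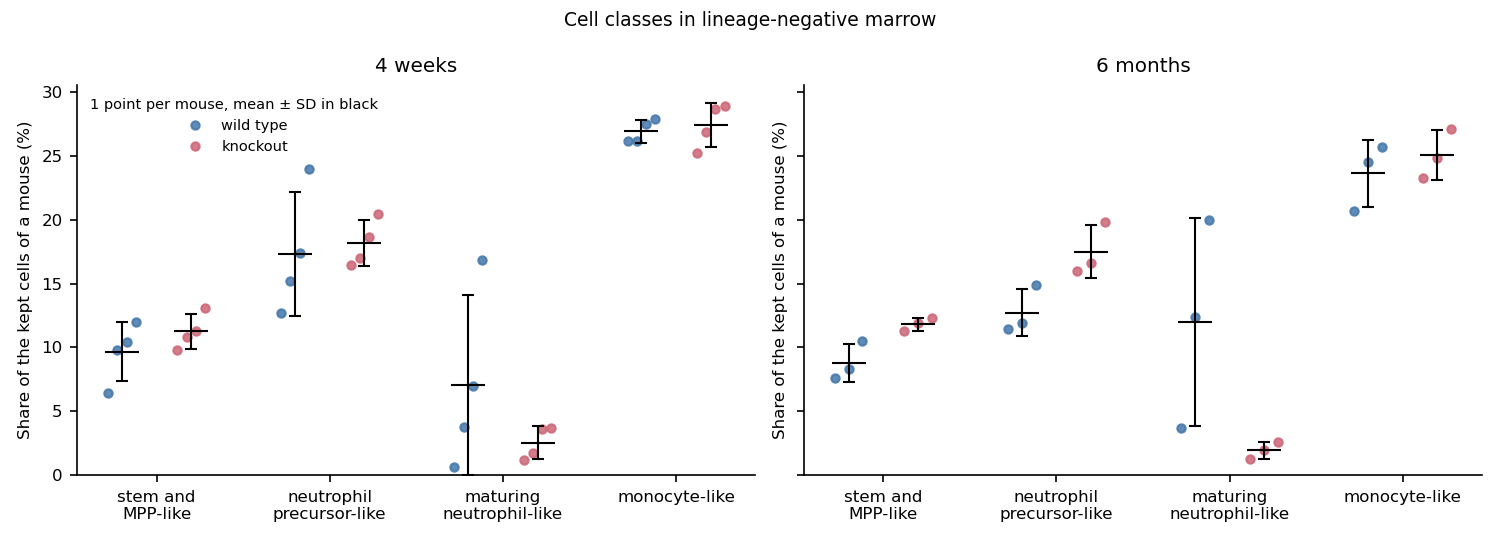
Share of each mouse's cells in percent by cell class, genotype and age, with points for mice and bars for the mean and SD. Maturing neutrophil-like cells made up 1.93% of knockout and 12% of wild type cells at 6 months, with wild type mice spread from 3.70 to 19.9%.

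The other classes differed less. Neutrophil precursor-like cells, which express Elane, Mpo and Prtn3, made up 17.5% ± 2.08 of knockout and 12.7% ± 1.86 of wild type cells at 6 months (exact p = 0.1) and 18.2% ± 1.80 and 17.3% ± 4.84 at 4 weeks (exact p = 0.800). Under 5% mitochondrial UMIs the 4-week shares turned to 3.06 and 11.5% (exact p = 0.0286). The mean number of maturing cells per precursor-like cell was 0.114 in the knockout and 1.0 in the wild type at 6 months (exact p = 0.1), and 0.143 and 0.507 at 4 weeks (exact p = 0.286). Stem and multipotent progenitor-like cells, marked by Hlf, Mecom and Cd34, made up 11.8% ± 0.513 and 8.79% ± 1.5 at 6 months (exact p = 0.1) and 11.3% ± 1.37 and 9.68% ± 2.35 at 4 weeks (exact p = 0.314; −3.79 points under 5% mitochondrial UMIs). With maturing cells left out of the total at 6 months, precursor-like cells made up 17.8 and 14.5% and stem-like cells 12 and 9.95%. Monocyte-like cells were 27.4 and 26.9% at 4 weeks (exact p = 0.629) and 25.1 and 23.6% at 6 months (exact p = 0.5), where the difference turned to −2.51 points with the higher minimum of genes per cell, −2.50 under 5% mitochondrial UMIs, −0.123 and −0.20 at Leiden resolutions 0.5 and 2 and −0.0456 without wild type mouse 2. Basophil and mast-like cells were 8.97 and 6.24% at 4 weeks (exact p = 0.114) and 7.32 and 8.91% at 6 months, erythroid-like cells 6.85 and 6.96%, then 8.76 and 6.85%, and B lineage-like cells 3.30 and 4.38%, then 1.55 and 3.66%. T and NK-like cells were 6.12 and 5.68%, then 8.80 and 7.77%, plasmacytoid dendritic-like cells 5.85 and 6.13%, then 5.78 and 5.79%, and conventional dendritic-like cells 2.06 and 2.42%, then 2.29 and 2.14%. Megakaryocyte-like cells were 0.783 and 0.810%, then 1.25 and 0.783%, and plasma cell-like cells 0.219 and 0.337%, then 1.48 and 1.57%, in the same order of genotype and age. Clusters that met no naming rule held 6.33% of knockout and 5.85% of wild type cells at 4 weeks and 6.29 and 5.27% at 6 months. The eosinophil-like class held 0 cells in every mouse, so 14 of the 15 classes could differ, and Benjamini-Hochberg adjusted p values over all 15 were at least 0.786 at 4 weeks and 0.5 at 6 months. At 4 weeks 0 classes had an exact p under 0.05, and at 6 months none could, since the smallest possible is 0.1. Without wild type mouse 1 at 4 weeks 3 classes had an exact p under 0.05, and without wild type mouse 4, 2.

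Stem and multipotent progenitor-like cells of the knockout had less RNA of the neutrophil alarmin genes S100a8 and S100a9, but so did other cell types. S100a8 fell by 1.14 ± 0.11 (SE, log2) at 4 weeks and 1.41 ± 0.15 at 6 months and S100a9 by 0.92 and 1.96 (edgeR adjusted p at most 2.65e-09). In T and NK-like cells, which do not make these proteins, S100a8 was lower by a like amount, at −1.62 and −2.0, with 99.3 ± 19.1 against 291 ± 59.9 CPM at 4 weeks (exact p = 0.0286). RNA free in the suspension and a difference between the libraries would both give this. Genes that fell at both ages were Nme2, a nucleoside diphosphate kinase (0.75 and 1.13), the mitochondrial calcium gatekeeper Micu1 (1.05 and 0.71), Nlgn2 (0.80 and 0.69), C1qtnf12 (0.88 and 0.55) and Phpt1 (0.69 and 0.62). At 6 months the call was lost in 5 of the 6 fits that leave out 1 mouse for C1qtnf12 and in 2 for Nlgn2. Nme2 also fell in T and NK-like cells at 6 months, by 1.71 (adjusted p = 0.00204). Chchd10 fell by 1.15 at 4 weeks and had −0.64 at 6 months (adjusted p = 0.126), or −1.13 without knockout mouse 2, where it passed. These are the 8 falls that the naming rule admits, and it admits 0 rises in this class. In all, edgeR called 812 genes higher and 1040 lower of 9555 at 4 weeks (n = 4 mice each) and 316 and 200 of 10371 at 6 months (n = 3). The mice of a genotype and age shared 1 library, so such calls cannot tell genotype apart from library. Scaled as the mean of per-cell CPM, the counts were 934 and 602, then 193 and 202. Relative to T and NK-like cells of the same mice, 4 genes passed at 4 weeks and 31 at 6 months, and S100a8 (0.51 and 0.54), S100a9 (0.27 and 0.50) and, at 6 months, Nme2 (0.58) turned upward without passing. T and NK-like cells share the genotype and held fewer UMIs per mouse (162902 to 335133 at 4 weeks, against 977188 to 2093967 in stem-like cells). Few calls in this contrast thus do not show that the changes were common to all cells.

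In these cells 38 of 43 cytosolic ribosomal protein genes fell and 2 rose at 4 weeks (39 and 2 when adjusted over the list alone; median −0.48), the opposite of the bulk direction. The list passed camera at an adjusted p of 2.32e-58, and at 0.0261 with an estimated correlation. At 6 months 13 rose and 6 fell (16 and 10 when adjusted over the list alone), with a median of −0.01 under an upward camera statistic (adjusted p = 6.55e-04, 0.671 with an estimated correlation). Oxidative phosphorylation genes fell at 4 weeks, 15 of 26 with 1 rise (16 and 1 when adjusted over the list alone; camera adjusted p = 7.59e-09, 0.258 with an estimated correlation). At 6 months 8 of them rose (8 when adjusted over the list alone; 0.00158 and 0.6). Of 40 MYC targets 16 fell and 2 rose at 4 weeks (17 and 2 when adjusted over the list alone; camera 0.009, 0.83 with an estimated correlation). At 4 weeks 5 more of the 26 lists tested had camera calls, and each had an adjusted p of at least 0.291 with an estimated correlation: primary granule (4 of 12 fell; 4 when adjusted over the list alone), secondary and tertiary granule (4 of 14 fell; 4), erythroid (5 of 11 fell and 2 rose; 5 and 3), monocyte (5 of 16 rose and 1 fell; 6 and 1) and cell cycle genes (6 of 30 rose and 1 fell; 6 and 1). Their camera adjusted p values were 0.00521, 0.0318, 0.0103, 0.0135 and 0.0324. Without the span trend the 4-week calls of MYC targets (0.104), primary granule (0.0574), secondary and tertiary granule (0.104) and erythroid genes (0.0574) were lost. The 4-week direction relative to T and NK-like cells turned for oxidative phosphorylation (median 0.09; 0.684), secondary and tertiary granule (0.27; 0.563) and cell cycle genes (−0.09; 0.752), as it did for secondary and tertiary granule genes at 6 months (0.29; 0.256). At 6 months, B lineage genes fell (6 of 11, and 7 when adjusted over the list alone; 1.88e-07, 0.136 with an estimated correlation), as did 6 of 21 stem cell genes (8 when adjusted over the list alone; 6.55e-04, 0.517). Interferon genes rose, 4 of 23 (9 rose and 1 fell when adjusted over the list alone; 2.94e-04, 0.420), and so did 3 of 21 immediate early genes (5 when adjusted over the list alone; 6.55e-04, 0.136) and 3 of 13 RNA polymerase II subunit genes (4; 0.0145, 0.347). Camera also called secondary and tertiary granule (5 of 16 fell and 1 rose, the same when adjusted over the list alone; 2.94e-04, 0.136), dendritic (2 of 12 fell, 3 when adjusted over the list alone; 0.00907, 0.403) and Hox genes (1 of 11 fell, 3 when adjusted over the list alone; 0.0145, 0.550).

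Neutrophil precursor-like cells carried higher Dusp6, a phosphatase that dampens ERK signalling, in the 6-month knockout (log2 1.05 ± 0.16, edgeR adjusted p = 8.72e-05), against 0.75 ± 0.52 at 4 weeks (adjusted p = 0.334). As for the shares, each genotype and age was 1 library, so p-values of single-cell genes and lists measure spread between mice within libraries. Genotype cannot be told apart from library in them. Grb10, an adaptor of insulin receptor signalling, rose by 1.04 at 6 months (0.0391), or 1.77 without wild type mouse 1, and had 0.58 at 4 weeks (adjusted p = 0.5). Nfia rose by 0.87 at 4 weeks (4.91e-04) and had 0.70 at 6 months (0.0555), where it passed without knockout mouse 3 (0.81) or wild type mouse 2 (0.88). Prss34, a mast cell protease, had 0.59 and 0.79 (0.419 and 0.416), and turned to −0.28 at 4 weeks with the higher minimum of genes per cell. Falls at both ages were Micu1 by 1.26 and 0.87, Abhd8 by 1.36 and 0.73, the homeobox gene Hoxa7 by 0.95 and 1.12 and the pseudogene Gm3839 by 1.15 and 0.82. The hemoglobin genes Hbb-bs, Hbb-bt and Hba-a1 fell at 4 weeks by 1.88, 1.55 and 0.69, and had −1.70, −1.41 and −1.25 at 6 months (adjusted p from 0.0581 to 0.0990). With marked doublets kept the 6-month values of Hbb-bt and Hba-a1 turned to 0.13 and 0.14, and at Leiden resolution 2 to 0.090 and 0.12. Without wild type mouse 1 the 6-month falls of Hbb-bs, Hbb-bt and Hba-a1 passed (−2.02, −1.65 and −1.46), as did that of Retnlg (−2.92; −1.84 without wild type mouse 2). Retnlg, a maturing neutrophil gene, fell by 2.19 at 4 weeks and had −2.55 at 6 months (adjusted p = 0.0992). Leaving out 1 mouse in turn lost the calls of Retnlg at 4 weeks in 5 of 8 fits, Hba-a1 in 1 and Grb10 at 6 months in 4 of 6. Hbb-bs was also lower in T and NK-like cells at 4 weeks (159 against 442 CPM; exact p = 0.0286), which do not make hemoglobin, and Retnlg stood at 2.20 against 10.2 CPM in precursor-like cells beside 4059 and 9701 CPM in maturing cells. EdgeR called 1629 genes higher and 1786 lower of 10194 at 4 weeks, and 540 and 423 of 10703 at 6 months. By mean per-cell CPM these were 2123 and 1155, then 337 and 727. The 6-month total of 963 became 615 without knockout mouse 1, 636 without knockout mouse 3 and 628 without wild type mouse 3. Relative to T and NK-like cells, 5 and 40 genes passed. At 4 weeks those cells held 162902 to 335133 UMIs per mouse, against 3606359 to 6767721 in precursor-like cells, which limits what this contrast can find.

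At 4 weeks 38 of 43 ribosomal protein genes fell and 2 rose in precursor-like cells (the same counts when adjusted over the list alone; median −0.41), 20 of 26 oxidative phosphorylation genes fell and 1 rose (20 and 1), and 7 of 14 primary granule genes fell (7). Camera's adjusted p values were 1.2e-26, 1.73e-10 and 0.00045, and with an estimated correlation 0.358, 0.354 and 0.707. The direction relative to T and NK-like cells turned for oxidative phosphorylation at 4 weeks (median 0.01; 0.969) and for RNA polymerase II subunits at 6 months (−0.09; 0.910). Knockout cells had a higher mitochondrial share of UMIs at this age (mean of mouse medians 5.08% ± 0.0452 against 4.07% ± 0.177, exact p = 0.0286) and not at 6 months (4.24 and 4.28%). At 6 months 17 ribosomal protein genes rose and 6 fell (17 and 10 when adjusted over the list alone; camera adjusted p = 1.72e-05, 0.849 with an estimated correlation). Erythroid genes fell, 4 of 15 with 1 rise (7 and 2 when adjusted over the list alone; 0.00315, 0.442), and interferon genes rose, 5 of 19 (6; 0.00436, 0.703). Oxidative phosphorylation (8 of 26 rose and 1 fell; 8 and 2; 1.72e-04, 0.703), RNA polymerase II subunit (3 of 13 rose; 3; 0.0145, 0.572) and plasma cell genes (2 of 4 rose; 2; 0.0177, 0.442) had upward calls. Hox (3 of 8 fell; 3; 0.0286, 0.703) and dendritic genes (1 of 8 fell, 4 when adjusted over the list alone; 0.0285, 0.442) had downward calls.

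Maturing neutrophil-like cells of the 4-week knockout had less RNA of the activation and immediate early genes Fos (log2 −1.56 ± 0.28, edgeR adjusted p = 1.54e-04) and Rgs2 (−1.33), of the chemokine Ccl6 (−1.71) and the protease inhibitor Slpi (−1.57), and of H2-Q10 (−1.89), Neurl3 (−1.40), Arl4c (−0.91) and the ferritin pseudogene Ftl1-ps1 (−1.06). The class joins less and more mature cells, in a balance given below. Whether the falls of these genes follow from that balance was not tested. None of these 8 passed at 6 months, with values from −1.24 for Fos to −0.40 for Slpi (adjusted p from 0.148). Without wild type mouse 1 several passed at that age: Fos (−1.47), Arl4c (−1.30), Rgs2 (−0.75), Ccl6 (−0.61), Slpi (−0.60), Lig1 (0.92), mt-Nd3 (0.81), Ndufc1 (0.77) and Nap1l1 (0.76). Rpl37a rose at both ages, by 0.52 and 0.73, and Rps28 at 6 months by 0.83, while Nap1l1, a histone chaperone, rose by 0.57 and Tcirg1, a proton pump subunit, by 0.57 at 4 weeks. Leaving out 1 mouse in turn lost the 4-week calls of Tcirg1 in 6 of 8 fits, Arl4c in 4 and Nap1l1 in 2, and the 6-month calls of Rps28 in 4 of 6 and Rpl37a in 2. The mitochondrial gene mt-Nd3 rose by 0.93 at 4 weeks beside the higher mitochondrial share named above, and also rose in T and NK-like cells (0.48 and 0.53). So did Rpl37a (0.32 and 0.49), Nap1l1 at 4 weeks (0.50) and Rps28 at 6 months (0.46), while Arl4c fell there at 6 months (by 0.49). Lig1, Hspd1 and Ndufc1 passed at neither age (log2 0.56, 0.39 and 0.40 at 4 weeks, and 0.88, 0.84 and 0.71 at 6 months). With marked doublets kept Hspd1 turned to −0.12 at 4 weeks. EdgeR called 335 genes higher and 348 lower of 3891 at 4 weeks and 17 and 1 of 4498 at 6 months, where 379 had an unadjusted p under 0.05. In these calls too, genotype cannot be told apart from library. By mean per-cell CPM these were 143 and 43, then 3 and 3. The 683 genes at 4 weeks became 405 without knockout mouse 3 and 438 without wild type mouse 4. The 18 at 6 months became 11 without knockout mouse 1, 6 without knockout mouse 3, 93 without wild type mouse 1 and 0 without wild type mouse 3. Relative to T and NK-like cells, 29 and 9 passed.

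In maturing cells at 4 weeks, 16 of 27 secondary and tertiary granule genes fell and 1 rose (17 and 1 when adjusted over the list alone; median −0.50), and 15 of 28 cell cycle genes rose (20 when adjusted over the list alone; median 0.60). Interferon genes fell, 5 of 7 (5; median −1.06), as did 6 of 13 immediate early genes (8; median −0.50). Camera's adjusted p values were 1.61e-09, 6.24e-09, 3.27e-05 and 2.11e-06, and 0.338, 0.247, 0.242 and 0.242 with an estimated correlation. The class joins less mature cells, rich in Ltf and Camp, with more mature ones, rich in Retnlg and Mmp9. Summed over mice, these were 161 and 101 knockout cells against 344 and 458 wild type cells at 4 weeks. Wild type mouse 4 alone gave 455 of the 802 wild type cells and wild type mouse 1 gave 17. The balance was not tested per mouse, so it is not taken as a genotype difference. Whether the 4-week changes of genes and lists in this class, the cell cycle rise among them, follow from it was not tested either. At 6 months camera called 5 of 18 lists, among them MYC targets upward (median 0.32; 1.84e-04, 0.199 with an estimated correlation) and ribosomal proteins upward (1 of 43 rose, 3 when adjusted over the list alone; 5.73e-06, 0.594). For MYC targets edgeR called 0 of 11 genes over all genes, with 4 at an unadjusted p under 0.05, and 4 rose when adjusted over the list alone. Oxidative phosphorylation was called upward (0 of 25 genes, 6 at an unadjusted p under 0.05; 0.0433, 0.518), a call lost without the span trend (0.12) and downward relative to T and NK-like cells (median −0.08; 0.977), and erythroid (0 of 7 and 4, with 1 fall when adjusted over the list alone; 2.44e-04, 0.463) and Polycomb genes (0 of 17 and 4; 0.0342, 0.407) downward.

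Monocyte-like cells of the knockout had more RNA of Galnt3, which starts mucin-type sugar chains, at both ages (log2 0.74 ± 0.19 and 0.84 ± 0.16, edgeR adjusted p = 0.00388 and 2.88e-04). Falls at both ages were Nme2 by 0.75 and 0.97, Micu1 by 1.0 and 0.85, the calcium sensor Guca1a by 1.17 and 0.56 and the inhibitory receptor Pilra by 0.95 and 0.78. Apoe, a lipid carrier, had −1.12 and −1.46 and S100a9 −1.23 and −0.84, with adjusted p values from 0.0845 to 0.130. At 4 weeks Apoe passed without knockout mouse 2 (−1.46) and without wild type mouse 1 (−1.34) and S100a9 without wild type mouse 1 (−1.48), and at 6 months S100a9 passed without knockout mouse 2 (−0.65) and without knockout mouse 3 (−1.05). At 6 months S100a9 relative to T and NK-like cells was higher, at 1.64 (edgeR adjusted p = 2.04e-14). It did not rise in monocyte-like cells but fell further in T and NK-like cells (log2 −2.47, edgeR adjusted p = 2.56e-41). In the same contrast Nme2 and Rpl27-ps3 turned to 0.76 and −0.45 (not past the threshold). Rpl27-ps3 rose by 0.53 and 0.81, and by 1.26 in T and NK-like cells at 6 months, and Gm3839 and Gm8797 fell by 1.19 and 1.02, then 0.81 and 0.87. Whether these pseudogenes share reads with near-identical copies was not tested. EdgeR called 1454 genes higher and 1670 lower of 10063 at 4 weeks and 725 and 639 of 10510 at 6 months. Here as well, genotype cannot be told apart from library. By mean per-cell CPM these were 1859 and 1087, then 462 and 909. The 1364 at 6 months became 891 without wild type mouse 3. Relative to T and NK-like cells, 1 and 97 passed, a contrast limited by the fewer UMIs of those cells.

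At 4 weeks 36 of 43 ribosomal protein genes fell and 3 rose in monocyte-like cells (36 and 3 when adjusted over the list alone; median −0.38), 20 of 26 oxidative phosphorylation genes fell and 2 rose (20 and 3), 7 of 14 primary granule genes fell and 1 rose (8 and 1), and 10 of 33 Polycomb, BAP1 and ASXL partner genes rose and 1 fell (14 and 2). Camera's adjusted p values were 7.28e-32, 8.98e-11, 0.0302 and 0.0302, and 0.321, 0.321, 0.520 and 0.321 with an estimated correlation. Without the span trend the primary granule (0.243) and Polycomb calls (0.0698) were lost. At 6 months 26 ribosomal protein genes rose (30 rose and 1 fell when adjusted over the list alone; median 0.12), 6 of 11 megakaryocyte genes rose (8; median 0.87) and 5 of 23 interferon genes rose (6). In the same cells 7 of 22 secondary and tertiary granule genes fell and 1 rose (10 and 1; median −0.41), and 8 of 20 monocyte genes fell (9). Camera's adjusted p values were 3e-26, 8.1e-07, 4.8e-04, 6.33e-08 and 2.1e-05, and with an estimated correlation 0.324, 0.212, 0.327, 0.295 and 0.327. Oxidative phosphorylation (9 of 26 rose and 1 fell; 9 and 1; 8.62e-05, 0.532) and primary granule genes (5 of 14 rose and 1 fell; 5 and 2; 0.0287, 0.324) also had upward calls. The direction relative to T and NK-like cells turned for megakaryocyte (median −0.41; 0.516), primary granule (−0.18; 0.543) and secondary and tertiary granule genes (0.08; 0.690) at 6 months and for oxidative phosphorylation at 4 weeks (0.03; 0.978). S100a8, a neutrophil gene, stood at 46.7 against 186 CPM in T and NK-like cells at 6 months (exact p = 0.1), and whether free RNA or a library difference lies behind this was not tested.

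**Figure D4:**
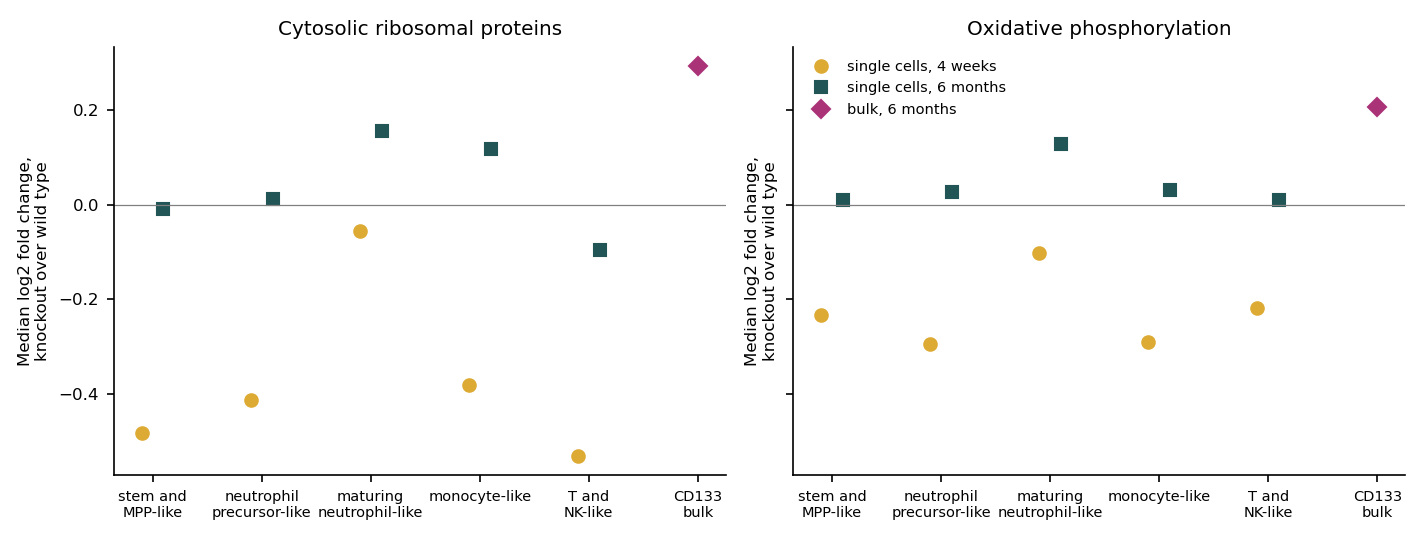
Median log2 fold change of cytosolic ribosomal protein genes (left) and oxidative phosphorylation genes (right) in the single-cell classes at both ages and in bulk marrow. Ribosomal protein genes lay below 0 at 4 weeks in stem-like (−0.48), precursor-like (−0.41), monocyte-like (−0.38) and T and NK-like cells (−0.53), and at 0.29 in bulk.

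The falls of ribosomal protein genes at 4 weeks extended to T and NK-like cells, which lie outside the myeloid lineage, where 33 of 43 fell and 1 rose (35 and 2 when adjusted over the list alone; median −0.53, camera adjusted p = 6.81e-50, 0.134 with an estimated correlation). The medians were also low in B lineage-like (−0.60), basophil and mast-like (−0.61), conventional and plasmacytoid dendritic-like (−0.54 and −0.49), erythroid-like (−0.46) and megakaryocyte-like cells (−0.53). In maturing neutrophil-like cells the median was −0.06, but −0.39 with marked doublets kept and −0.16 with the higher minimum of genes per cell. Set against T and NK-like cells, the 4-week medians of the list turned upward, to 0.04 in stem-like, 0.05 in precursor-like, 0.11 in monocyte-like and 0.38 in maturing cells. The 6-month medians in that contrast were 0.11 in stem-like, 0.15 in precursor-like, 0.27 in monocyte-like and 0.12 in maturing cells. By mean per-cell CPM the 4-week medians stayed downward in stem-like, precursor-like and monocyte-like cells, at −0.45, −0.33 and −0.32. With that scaling the median was 0.16 in maturing cells at 4 weeks against −0.06 from summed UMIs, and −0.04 against 0.01 in precursor-like cells at 6 months. These further classes, T and NK-like cells as a reference, the test of 4 weeks alone and Micu1 as a gene to follow were chosen after the values were seen. Micu1 was lower in each of the 7 classes that tested it at 4 weeks, 6 of them past the threshold, in each of 8 at 6 months, 5 of them past it, and in bulk marrow (log2 −0.78 ± 0.07, edgeR adjusted p = 0.00036). Among genes called at both ages, 88 changed in the same direction and 138 in opposite directions in stem-like cells, 257 and 237 in precursor-like cells, 2 and 3 in maturing cells and 283 and 297 in monocyte-like cells. Across genes, the log2 fold changes at the 2 ages correlated weakly (Pearson's r from 0.0273 to 0.128).

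Bulk marrow and single cells at 6 months shared more rises than their numbers alone would give. Of the bulk rises, 81 also rose in stem-like cells against 26.7 expected, 110 in precursor-like cells against 44.8 and 134 in monocyte-like cells against 61.3, though matching on expression level and gene span raised the expected numbers to 53.3, 76.8 and 97.9. Shared falls numbered 8 against 15.6 (13.6 when matched), 14 against 35.6 (25.7) and 48 against 55.2 (53.5), and 40, 77 and 94 genes were called in opposite directions. Called in bulk and in all 3 of these classes were 79 genes, 74 higher and 5 lower, the 5 being Asxl1, Micu1, the linker histone gene H1f0, Mansc1 and Prkar2a, a regulatory subunit of protein kinase A. How many genes chance would put in all 3 was not computed, and the classes share mice and libraries. At 4 weeks Asxl1, Micu1, Rpl37a, Rps15 and the splicing gene Snrpd3 were called in the same direction in these classes too, while 49 of the 74 were called lower in all 3, among them Cox5b (−0.90, −0.89 and −0.88). These names were chosen after the values were seen.

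The peak lists cover both genotypes together, so they describe where each mark lies and not what the knockout alters. H3K27me3, the Polycomb mark of silenced genes, was profiled in CD133-purified cells (5 knockout and 5 wild type libraries), in sorted populations that the labels name GP and BMN and in Ly6G-purified blood neutrophils named PBN (3 and 3 each), and in a population named MP (2 and 2). At a q of at most 1e-06, the lists held 11685 peaks in CD133 cells, 7376 in GP, 9198 in BMN, 14597 in PBN and 42369 in MP, and the GP and BMN peaks were wide (medians 2740 and 1946 bp) and the MP peaks narrow (553 bp). CD133 peaks overlapped 91.5% of GP peaks (Clopper-Pearson 95% interval 90.8 to 92.1), 80.1% of BMN peaks (79.3 to 80.9), 55.6% of PBN peaks (54.8 to 56.5) and 21.1% of MP peaks (20.7 to 21.5). In the other direction the order was nearly the reverse, with 83.7% of CD133 peaks met by PBN peaks, 79.6% by MP, 71.3% by BMN and 66.4% by GP, so neither order ranks the populations by likeness to CD133 cells. The intervals cover counting error only. Of the CD133 peaks, 6029 (51.6%) were overlapped in all 4 other lists and 359 (3.07%) in none. The widest domain of GP, BMN and PBN lay on chromosome 15, at 102907973 to 103018231 in GP (110259 bp), 102908030 to 103023861 in BMN (115832 bp) and 102907177 to 103020890 in PBN (113714 bp). In CD133 cells the widest were on chromosome 8 at 123537327 to 123626017 (88691 bp), chromosome 15 at 102915833 to 102993686 (77854 bp) and chromosome 6 at 52208144 to 52278396 (70253 bp). The widest MP peak was the same chromosome 8 domain, at 123537454 to 123625816 (88363 bp), followed by peaks on chromosomes 14 and 2. The genome build is not given in the sources used here, so the positions were not matched to genes.

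**Figure D5:**
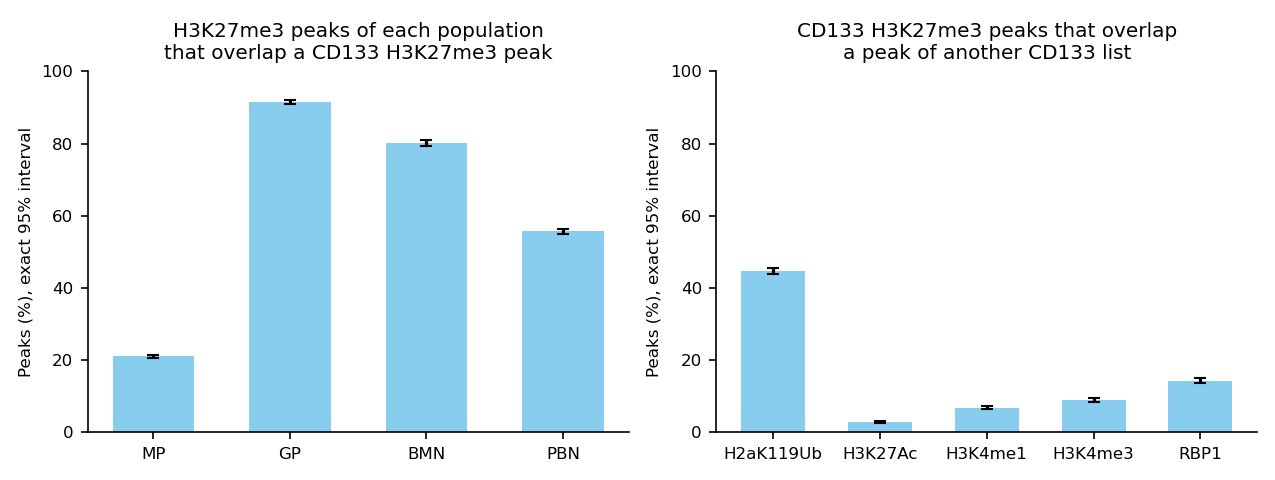
Percent of H3K27me3 peaks in each sorted population overlapped by a CD133 H3K27me3 peak (left, with 95% Clopper-Pearson intervals) and percent of CD133 H3K27me3 peaks overlapped by each other CD133 list (right, with the same intervals). Overlap ran from 91.5% of GP peaks to 21.1% of MP peaks, but GP peaks met 66.4% and MP peaks 79.6% of the CD133 peaks.

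Within CD133-purified cells, H3K27me3 peaks met H2aK119Ub peaks more often than peaks of active marks, while H2aK119Ub peaks met several marks. Ubiquitinated histone H2A (H2aK119Ub, 29237 peaks; 5 knockout and 4 wild type libraries), the mark that BAP1 removes, overlapped 44.7% of the CD133 H3K27me3 peaks. H3K27Ac, found at active enhancers and promoters (29917 peaks; 5 and 4), overlapped 2.94%, H3K4me1 (38206; 2 and 2) 6.82% and the promoter mark H3K4me3 (12542; 2 and 2) 8.99%. RBP1, as the labels name it (55771 peaks; 4 and 4), overlapped 14.4%. Of H2aK119Ub peaks, 36.2% met an RBP1 peak, 28.3% an H3K27me3 peak, 25.7% an H3K4me1 peak, 18.2% an H3K27Ac peak and 15.4% an H3K4me3 peak. Of H3K4me3 peaks, 83.0% met an H3K27Ac peak, 82.2% an RBP1 peak and 32.4% an H2aK119Ub peak. The overlap that chance would give was not measured. Each list was kept at the threshold its authors chose, which differs between marks, so numbers of peaks are not comparable between marks.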

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

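Of the tests in this part, those of ribosomal proteins in T and NK-like cells and in thinned cells, of the minimum of genes per cell, of unequal purification and of the median over splits were chosen after the results were seen, as was the restriction of the single-cell ribosomal tests to 4 weeks, since they first covered both ages.

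In 16 of 294 groups of 4 samples, 1 sample stood apart, its gap to the nearest other, divided by the group's range, being over Dixon's 95% critical value, a mark that chance gives in about 1 in 20 groups. In bulk wild type libraries 1 library was high for Cbl (182 CPM against 103 to 114 in the others; ratio 0.863), Klf5 (37.5 against 28.3 to 29.7; 0.852) and Polr2b (92.4 against 70.3 to 72.4; 0.904), and low for Stfa1 (3.58 against 4.89 to 5.08; 0.873). In knockout libraries 1 was high for Nfkb1 (138 against at most 122; 0.859) and 1 low for Penk (4.74 against 8.41 to 8.97; 0.867). Among 4-week mice 1 knockout was low for the share of plasma cell-like cells (0.115% against 0.240 to 0.260%; 0.861). In maturing neutrophil-like cells 1 knockout mouse was low for Ccl6 (233 CPM against 372 to 379; 0.951) and 1 wild type mouse for mt-Nd3 (129 against 226 to 237; 0.894). In monocyte-like cells 1 wild type mouse was high for Asxl1 (67.8 against 62.5 to 63.4; 0.832) and 1 knockout low for Galnt3 (7.50 against 12.3 to 12.8; 0.904). In precursor-like cells 1 wild type mouse was high for Hbb-bs (142 against 105 to 111; 0.839) and Hbb-bt (93.4 against 58.9 to 63.4; 0.870). In stem-like cells 1 wild type mouse was high for Chchd10 (38.9 against 24.8 to 27.2; 0.831) and for S100a8 (103 against 92.9 to 94.5; 0.841), and 1 knockout low for S100a8 (36.4 against 45.0 to 46.1; 0.886).

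The knockout change differed between ages, tested as an interaction in edgeR, where age cannot be told apart from library. Genes with an adjusted p under 0.05 for the difference numbered 1136 in stem-like, 2245 in precursor-like, 180 in maturing and 2324 in monocyte-like cells. Asxl1 fell further at 6 months than at 4 weeks, by −0.54 (log2) in stem-like cells, −0.70 in precursor-like cells and −0.59 in monocyte-like cells (adjusted p = 0.0123, 9.08e-05 and 1.12e-04), but not in maturing cells (0.08, not past the threshold). The median of the ribosomal protein genes was higher at 6 months by 0.54 in stem-like, 0.51 in precursor-like, 0.28 in maturing and 0.58 in monocyte-like cells.

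Antibody tags other than the hashtags were not used in the report and carried signal. Over the kept cells of the 4 libraries CD48 had 6885601 counts, Fcgr 6374628, cKit 4240631, Slamf1 1614985, Eng 1439773 and Ly6a 1100954, against 10 for Itga2b. Except for Itga2b, with a median of 0 in each library, their medians per cell were higher at 6 months than at 4 weeks in both genotypes. For cKit they were 73 and 50 in knockout and wild type against 7 and 5. No tag served as a control without a target.

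The fall of ribosomal protein genes in 4-week knockout cells was weighed against 3 technical explanations. A difference between the libraries that every cell type shares would lower them in T and NK-like cells too, and there their median was −0.53, against −0.41 in precursor-like cells. With every precursor-like cell thinned to 2000 UMIs the median was −0.41. Random thinning keeps the expected share of each gene, so it cannot decide whether depth plays a part. The gene span trend is not the whole cause, since 0.618 of the median (95% bootstrap interval 0.555 to 0.724) stayed without it. A library-wide difference, or a genotype effect in every lineage, may explain the fall, and the design gives 1 library per genotype at this age.

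The rise of ribosomal protein genes in bulk was weighed in the same way. A trend with expression level is excluded, since the list median of 0.29 lay above the 95th percentile of expression-matched random lists (0.0485) and above the highest of them (0.127). Without the gene span trend 0.597 of the median stayed (95% bootstrap interval 0.408 to 0.624, which spans 0.5), so how much of the rise the trend accounts for cannot be told apart. By camera p chance is not excluded, since 2 of the 35 splits of the 8 libraries gave one as small (3.5e-24 for the real split and 5.92e-29 for the smallest other). The size of the median was largest in the real split (0.292 against at most 0.208 in the others), so the 2 measures differ and the source of the rise stays open.

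The lower share of maturing neutrophil-like cells at 6 months was set against 3 technical explanations. It is not due to the minimum of genes per cell, since with 200 genes the ratio of mean shares was 0.154, nor to genes that differ between genotypes and define the clusters, since without them it was 0.164. Unequal purification cannot be told apart from genotype, because each genotype was 1 library, and 1 wild type mouse lay below the highest knockout mouse at 4 weeks (0 at 6 months). No biological explanation of the lower share was tested.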

How the results depend on the processing

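Changes relative to T and NK-like cells, removal of the gene span trend, the minimum of 200 genes per cell, clusters without called genes and the edgeR test of cell numbers were chosen after seeing the data. Of 3108 values for named genes and shares under all alternatives, 2753 kept their direction and side of the threshold, 262 lost the threshold, 47 gained it and 46 reversed. The causes of the changes below were not tested unless named.

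Over other scalings, tools, filters and dispersion fits, bulk genes higher ranged from 919 to 1075 and lower from 893 to 1044. The test against a fold of 1.2 left 38 higher and 93 lower, since it asks for larger changes, and Asxl1, at −0.37, did not pass it. With the gene span trend removed 603 were higher (482 shared) and Elane was −0.0052. A replicate block, pairing libraries by column number, gave 649 higher genes (632 shared) and 4 lists (2 shared), but libraries of equal number did not resemble each other (correlations of their deviations −0.305 to −0.0262; for 0 of 8 libraries was the own number the closest), so the numbers are not taken as pairs. With an estimated correlation 0 lists moved. Leaving out 1 library in turn gave 519 (without W4) to 953 higher genes, 2 to 6 lists (6 without W5) and −0.41 to 0.21 (without M2) for Hoxa9, which is near the detection limit.

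Thinned to 2000 UMIs per cell, which removes counts and shallow cells, genes called at 4 weeks and 6 months were 811 and 206 in stem-like, 1400 and 275 in precursor-like, 260 and 5 in maturing and 1757 and 630 in monocyte-like cells. Maturing cells had 186 and 6 with mean per-cell CPM, 357 and 145 with a higher minimum of genes per cell, and at 6 months 54 with marked doublets kept and 35 at Leiden resolution 0.5. Prss34 in 4-week precursor-like cells was −0.28 with that minimum. With doublets kept Hbb-bt and Hba-a1 were 0.13 and 0.14 in 6-month precursor-like cells (0.090 and 0.12 at Leiden resolution 2), and Rps28 and Hspd1 −0.063 and −0.12 in 4-week maturing cells. Leaving out 1 mouse gave 615 (without knockout 1) to 972 in precursor-like cells at 6 months, 405 (without knockout 3) to 706 in maturing cells at 4 weeks and 0 (without wild type 3) to 93 (without wild type 1) at 6 months (with edgeR, 379 at an unadjusted p under 0.05 with all mice), and 891 (without wild type 3) to 1277 in monocyte-like cells at 6 months.

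Relative to T and NK-like cells of the same mice, 4 genes at 4 weeks and 31 at 6 months passed in stem-like, 5 and 40 in precursor-like, 29 and 9 in maturing and 1 and 97 in monocyte-like cells. T and NK-like cells share the genotype and held fewer UMIs per mouse than stem-like, precursor-like and monocyte-like cells. The drop in calls therefore does not show that the changes were common to all cells. The 4-week Asxl1 value became 0.16 in stem-like, 0.30 in precursor-like, 0.0028 in maturing and 0.31 in monocyte-like cells, none past the threshold. In stem-like cells S100a9 was 0.27 at 4 weeks and 0.50 at 6 months, S100a8 0.51 and 0.54, and Nme2 0.58 at 6 months. At 6 months Tcirg1 was −0.0063 and Hspd1 −0.15 in maturing cells, and Rpl27-ps3 −0.45, S100a9 1.64 and Nme2 0.76 in monocyte-like cells. The S100a9 value was reversed and past the threshold (edgeR adjusted p = 2.04e-14), with S100a9 at −2.47 in the T and NK-like cells themselves. This alternative gave no value for 48 gene results.

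Of the class shares, 0 had an exact p under 0.05, but 1 did by marker score, 1 with a higher minimum of genes per cell and 3 under 5% mitochondrial UMIs, and 0 to 3 without 1 mouse (3 without wild type 1 at 4 weeks). The precursor-like share at 4 weeks differed by −0.191 points by marker score, −8.46 under 5% mitochondrial UMIs (reversed, exact p = 0.0286) and −0.703 to 3.05 without 1 mouse, and the stem-like share at 4 weeks by −3.79 under 5% mitochondrial UMIs, a limit that removes more knockout cells at that age, whose mitochondrial share was higher. The monocyte-like share at 6 months differed by −2.51 with the higher minimum of genes, −2.50 under 5% mitochondrial UMIs, −0.123 and −0.20 at Leiden resolutions 0.5 and 2 and −0.0456 to 2.48 without 1 mouse, and at 4 weeks by −0.261 at resolution 2. The megakaryocyte-like share at 4 weeks differed by 0.00761 with the higher minimum of genes, 0.0533 with doublets kept, 0.0346 with at least 200 genes and −0.123 to 0.114 without 1 mouse, and the erythroid-like share by −0.480 to 0.451. The maturing share differed by −6.68 (without wild type 1) to −1.25 at 4 weeks without 1 mouse, and by log2 −2.64 in the edgeR test at 6 months.

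Overlap of MP, GP, BMN and PBN peaks with CD133 peaks was 22.1, 92.8, 82.0 and 57.8% at the authors' own thresholds and 16.9, 87.2, 73.8 and 46.1% with at least 0.5 of a peak covered, and of MP, GP and BMN 23.8, 90.5 and 78.8% at a q of at most 1e-10. Of CD133 H3K27me3 peaks, H2aK119Ub covered 45.6% with all marks at a q of at most 1e-05 and RBP1 10.8%. With at least 0.5 covered the shares were 27.5% for H2aK119Ub, 0.987% for H3K27Ac, 1.83% for H3K4me1, 3.21% for H3K4me3 and 3.86% for RBP1. The promoter comparison and its alternatives (window, threshold, background, DESeq2 calls) were not run, as no build is named.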

Other observations

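All tests in this part were written down before their results were seen. Of 35 splits of the 8 libraries, only the real one gave as many higher genes in bulk (981, highest other 1). The same held for lower genes (969, highest other 1). The other splits mix genotypes within a group, so any difference between genotypes or their libraries lowers the counts there. The splits thus show a first rank among 35, and a difference between libraries that follows genotype is not excluded. The count of lists differs, as 35 of 35 splits gave at least the real 2 lists and 1 gave 18. This may point to a structure of the samples that moves gene lists together whatever the genotype, or to a preset correlation that is too low, since 0 lists moved with an estimated one. The trend of fold change with gene span was as large in 1 of 35 splits, the real one (rank correlation 0.376 in size, highest other 0.335). The real split thus ranked first by a narrow margin, and a difference between libraries that happens to follow genotype is not excluded.

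In single cells at 4 weeks 1 of 35 splits of the mice, the real one, gave as many genes in each class. Counts were 1852 against a highest other of 6 in stem-like and 3415 against 14 in precursor-like cells. They were 683 against 120 in maturing and 3124 against 12 in monocyte-like cells. These splits mix genotypes within a group as well, so they show a first rank among 35. A difference between the libraries is not excluded. At 6 months the 10 splits are too few for a share under 0.05, and real counts and highest others were 516 and 0, 963 and 1, 18 and 7, and 1364 and 0.

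A stretch of foreign chromosome carried along with the targeted Asxl1 locus was tested as a source of the bulk changes. Among the 20 tested genes nearest to Asxl1, 1 was called (Bcl2l1), and the ratio of shares called there and among all others (18%) was 0.278 (Fisher's exact 2-sided p = 0.237; upper limit 1.38), which is below the 2-fold enrichment such a source needs.

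Over all genes, the fold changes of bulk marrow and single cells did not correlate beyond what other splits gave. Even so, 79 genes were called the same way in bulk and in stem-like, precursor-like and monocyte-like cells at 6 months. Of these 74 were higher and 5 lower, Asxl1 and Micu1 among the lower. At 4 weeks 49 of the 74 were called lower in each of these classes. The classes share mice and libraries, and how many genes chance would give was not computed. The correlation of edgeR log2 fold changes across genes was 0.0485 for stem-like cells at 6 months. From differences of mean log CPM, the measure used for the splits, it was 0.0378 in size, and 145 of 350 pairs of splits gave one as large (highest other 0.133). For precursor-like cells it was 0.0196, with 278 of 350 pairs as large (highest other 0.236).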
